A study of Mus musculus with 2 samples.

How the data were processed

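ARID4B ChIP-seq was done on 1 pool of 108 wild type testes of postnatal day 1.5 mice of a mixed C57BL6/J and 129/SvEv background, with 1 input library as the control. Per the submitters' processing notes, BWA and MACS were used and the build was mm9. Versions, parameters, filters and the treatment of reads that map to several places are not given in the sources used here. The authors deposited 1 list of intervals for the ChIP library, with a chromosome, a start, an end, a running number and a value for each interval. The numbering ran without a gap. Only this list was used. Aligned reads, coverage and the input library's own values were not analysed here, so the depth of either library and its effect on the lowest detectable enrichment are unknown.

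The value of each interval is treated here as a score that the authors deposited. The name under which the list was deposited calls it a p-value, but all values exceed 1, the lowest lying just above 70. That would be 10 times the negative log10 of p, the scale of early MACS versions with a limit of 1e-07, which no source states. Scores were used within this list only, to describe, rank and filter intervals, to compare medians between groups of intervals or genes, and to set a cut for the X chromosome under the assumption that score is proportional to depth. Larger scores went with wider intervals (Spearman's rho 0.61 across intervals, which are not independent replicates).

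The sources disagree on the build: the deposited list is named for mm10 while the notes name mm9. Start and end positions were compared with a RefSeq gene table of GRCm38.p6, the same build as mm10. In place, 80.26% of the intervals lay within 1 kb of a protein-coding gene end, between 73.01 and 84.82% on single chromosomes. Shifted by 2 kb the share was 28.63 or 29.25%, by 5 kb 12.92 or 13.27%, and by 200 kb 9.54 or 9.94%. The intervals were therefore read as GRCm38. Whether the reads were aligned to it or the intervals were moved from mm9 is not known. Positions are printed counting from 1.

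The gene table gives the start and end of each gene but no strand, transcripts, exons or sequence. The design fixed before the data were examined had planned starts of transcription, exon classes, CpG content, motifs and distances signed by strand. Starts of transcription were replaced by both ends of the gene record, a gene being counted when an interval overlapped (by at least 1 bp) the 1 kb either side of an end. Exon and UTR classes, CpG content and motifs were left out. Genes were taken on the assembled chromosomes (21887 protein-coding). A gene's interval is the best-scoring one at either end. An end close to 2 genes counts for each, and such sharing is named.

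Shuffles (1000) moved each interval to a random place on its own chromosome, between the first and the last annotated gene, since assembly gaps were not known. Lists of genes (22) were fixed before the data were examined. Members were matched by symbol, or by an older symbol where no gene bears it now, and members that are not protein-coding were left out. Each list's share of genes with an interval was set against 10000 random lists of the same size drawn from all protein-coding genes (two-sided permutation p, Benjamini-Hochberg over the 22 lists, threshold 0.05). Pairs of lists (7), chosen after the data were examined, were compared with Fisher's exact test, adjusted over the 7, and again under the alternatives below that can change the counts. Median scores were compared with 100000 label permutations. Genes and intervals are not replicates, and these p-values describe this list only. Intervals on shares are 95% Clopper-Pearson and cover counting error only, and the limit given for a share of 0 is 3 genes of the total.

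The rule for named genes, also fixed beforehand, took the 20 protein-coding genes with the best-scoring intervals, up to 4 best members of each list, the 5 best intervals over 5 kb from a gene end, and 14 genes named with or without an interval (Arid4a, Arid4b, Rb1, Sox9, Wt1, Gata4, Amh, Gdnf, Kitl, Cxcl12, Fgf2, Dhh, Snrpn and Ddx4). Midn, Tnrc18, Smad7, other list members, X-linked genes and members without an interval were named after their values were seen.

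Alternatives were intervals scoring above the median, windows of 500 bp and 5 kb, the midpoint in place of any overlap, protein-coding ends only, shuffles over all chromosomes, and genes without a second gene end within 1 kb. Added after the data were examined were random lists matched on deciles of gene length, genes with a curated transcript, autosomes only, intervals anywhere in the gene record, and a gene-end class that reaches 5 kb outside the record. The overlap, shuffle and list steps were tested on simulated data. Of 60% of intervals planted at gene ends 60.0% were recovered. For lists of 40 genes among 21887, 4.6% of 500 unchanged lists, 41.4% at 1.5 times and 91.6% at 2.0 times the background share gave an unadjusted p under 0.05. The simulated genes were independent of each other. The rates may therefore not hold for lists of neighbouring genes that share intervals, such as Hox, histone and receptor genes. Python 3.11.15 was used with numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9.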

Results

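The study asked where ARID4B, an AT-rich interaction domain protein of the SIN3-histone deacetylase complex, sits on chromatin in the newborn mouse testis, at the age when the niche for the first spermatogonial stem cells forms. Chromatin from wild type testes at postnatal day 1.5, pooled from 108 testes, was immunoprecipitated with an antibody against ARID4B and sequenced beside input DNA. There was 1 ChIP library and 1 input library, so no value below has a replicate, and every test describes this single list of enriched intervals rather than the spread between animals. Input DNA was the only control here, so how much of the signal depends on ARID4B was not tested. The list held 6632 intervals that did not overlap each other, covering 7.86 Mb on the 19 autosomes and the X chromosome. Interval widths had a median of 1084 bp (quartiles 888 and 1367 bp, largest 5930 bp). Each interval carried the authors' own evidence score, with a median of 125.0, a lowest value just above 70 and a highest value of 1760.61. The number of reads in either library is not known from the values used here, so the depth behind an interval is unknown.

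ARID4B intervals lay almost entirely at genes, and mostly at gene ends. Of the 6632 intervals, 5600 (84.44%) overlapped the stretch within 1 kb of an end of an annotated gene record, against 9.76% ± 0.36 (SD over 1000 shuffles) for the same intervals moved at random along their chromosomes. For protein-coding genes alone the share was 80.26%, against 4.99% ± 0.27. Midpoints lay a median of 379 bp from the nearest gene end, and 1447 intervals (21.82%) had their midpoint inside a gene record but over 1 kb from its ends. Only the outer ends of a record are known here, so some of these 1447 may lie at starts of transcription inside a record. Only 76 intervals (1.15%) lay between genes, where 48.14% ± 0.60 of the shuffled midpoints fell. None of the 1000 shuffles had as high a share at gene ends (one-sided permutation p = 0.001, the smallest they can give).

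The gene table used here gives no strand, so a start of transcription could not be told from a transcript's other end by annotation. The data were nevertheless one-sided. Among protein-coding genes over 10 kb long with no second gene end within 1 kb, 2890 had an interval at a single end and 23 had intervals at both (0.79% of those with any). At those 2890 genes the interval midpoint lay a median of 326 bp inside the gene record (quartiles 177 and 578 bp), and inside rather than outside it in 91.87%.

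**Figure D1:**
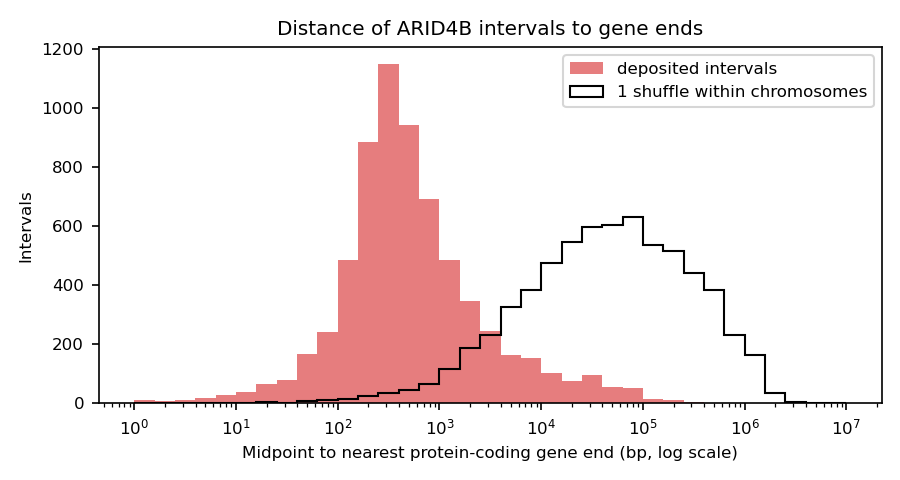
Distance from each interval's midpoint to the nearest protein-coding gene end (bp, log scale) for the 6632 deposited intervals (filled) and for 1 shuffle of them within their chromosomes (line), as numbers of intervals per bin. The deposited intervals gather within 1 kb of a gene end, with a median of 422.5 bp, while shuffled midpoints lie mostly far over 1 kb away.

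Intervals near gene ends had higher scores than those far from them. The median score was 126.4 for the 5109 intervals with a midpoint within 1 kb of a gene end and 105.9 for the 427 intervals over 5 kb from any (difference 20.5, two-sided permutation p = 1e-05, the smallest that 100000 resamples can give). The share of intervals overlapping the 1 kb stretch at a gene end was 73.8% in the lowest decile of scores and 90.96% in the highest. Intervals of the highest decile were also wider (median 1754 bp against 855 bp in the lowest), and a wider interval reaches the stretch more easily. The 5 best intervals over 5 kb from any gene end all lay inside gene records. They were at 13:63562912-63566458 in Ptch1, the Hedgehog receptor (score 1261.13), at 14:63239618-63242012 in Gata4, a transcription factor of gonadal somatic cells (894.01), at 13:37825357-37828251 in Rreb1 (753.34), at 11:69408172-69412349 in Kdm6b, a histone H3 lysine demethylase (549.15), and at 8:47287473-47289893 in Stox2 (545.48). Starts of transcription inside a record are not known here, so some of these 5 intervals may lie at one. All coordinates are on mouse build GRCm38.

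Of 21887 protein-coding genes, 5930 (27.09%, 95% Clopper-Pearson interval 26.51 to 27.69%) had an ARID4B interval at a gene end. Of these genes, 2266 (38.21%) had the end of a second protein-coding gene within 1 kb, and 894 of the 5156 intervals that were the best of any gene were the best of 2 or more genes. The highest score in the list, 1760.61, was at Zfp36l2 (17:84184950-84187392), which encodes an RNA-binding protein that promotes decay of AU-rich messages. Next came Irf2bp2 (8:126591005-126593527), a corepressor gene, with 1641.15, and its relative Irf2bpl was also among the best 20 genes with 1131.25. The interval at 11:75164932-75169661 (score 1584.47) lay inside Hic1, a transcriptional repressor gene, and within 1 kb of an end of Smg6. The interval of rank 4, and the widest, lay inside Midn over 1 kb from its ends (10:80147464-80153393, 1535.07), and beside those in Ptch1 and Gata4 the others of the 20 best with no protein-coding gene end within 1 kb were in Tnrc18 (848.37) and Smad7 (848.3). The interval at 17:34117800-34123221 (1314.68) reached both Brd2, a bromodomain protein gene, and H2-DMa.

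Among the rest of the best 20 genes were the transcription factor genes Gata6 (score 1114.18), Sox4 (964.74), Zfp703 (922.31) and Mafa (876.04). Mex3b, an RNA-binding protein gene (1245.12), Tsc22d2 (1160.13), Ptma, the prothymosin alpha gene (1026.46), Arhgef17 (964.78), Zmiz1 (821.23) and Fam222a (809.76) had intervals not shared with another protein-coding gene end. The interval at the splicing factor gene Srsf2 (795.71) was shared with Mfsd11, and that at Psma7, a proteasome subunit gene (938.92), with Ss18l1.

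Genes of ARID4B's own complex were among those with intervals. Of 21 genes of the SIN3-HDAC complex and the retinoblastoma family, 14 (66.67%) had an interval, against 27.10% in random lists of the same size (two-sided permutation p = 0.0004, adjusted p = 0.0011 over 22 lists). They included the paralog Arid4a (12:71014890-71016833, score 639.41), Ing2 (540.77), Sinhcaf (450.42), Sin3a, the scaffold of the complex (402.47), and Hdac1 (372.07, shared with Marcksl1). All 3 retinoblastoma family genes were among them, with scores of 82.68 at Rb1, 143.5 at Rbl1 and 155.97 at Rbl2. Arid4b itself had none, the nearest interval lying 322.5 kb from its record, and Hdac2, Ing1, Brms1, Brms1l, Sap18 and Sap130 had none at an end. A high share was not particular to this list: cytosolic ribosomal protein genes had 65.0% and cytoskeleton genes 72.5%. The random lists drew on all protein-coding genes, olfactory receptor genes included, and no list was set against expressed genes alone.

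Cell growth and division genes carried intervals more often than random lists. Of 80 cytosolic ribosomal protein genes 52 (65.0%) had an interval, led by Rps6 (683.86), Rpl32 (654.1), Rpl13 (640.33) and Rpl12 (619.44, shared with Lrsam1). Of 68 core spliceosome and RNA-binding genes 40 (58.82%) had one, with Srsf2, Hnrnpk (699.97, shared with Rmi1), Hnrnpu (560.4) and Prpf4b (507.45) first. Both lists had an adjusted permutation p of 0.00073, the smallest that 10000 random lists could give here. Of 40 RB-E2F cell cycle genes 22 (55.0%) had an interval (adjusted permutation p = 0.0015). They held all 5 E2F genes of the list, E2f3 with 630.03, E2f8 with 395.16, E2f2 with 243.0, E2f1 with 147.27 and E2f7 with 137.11, the cyclins Ccne2 (337.08), Ccnb1 (310.05) and Ccna2 (278.0, shared with Bbs7), and the mitotic kinase gene Cdk1 (307.7). Pcna, Ccne1, Cdc6 and Mcm2 had none.

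Oxidative phosphorylation genes did not stand out in the same way. Intervals were found at 27 of 83 nuclear-encoded genes (32.53%, adjusted permutation p = 0.43), the best at Ndufb10 (455.08, shared with Rps2), Cox6c (386.35), Cyc1 (265.44) and Ndufa13 (250.92, shared with Tssk6). The ribosomal protein list differed from them (odds ratio 3.85, Fisher's exact two-sided p = 4.2e-05, adjusted p = 0.0003 over 7 pairs of lists). Proteasome subunits lay in between, with 17 of 39 genes (43.59%, adjusted permutation p = 0.089), and passed the threshold with windows of 500 bp or 5 kb (adjusted permutation p = 0.043 and 0.019) and when the midpoint had to lie in the window (0.036). Psma7, Psmd7 (334.49), Psmd11 (192.98) and Psmd1 (154.94) came first.

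The cytoskeleton list and the list of receptors and effectors of developmental signalling pathways held the highest shares. Of 40 cytoskeleton genes 29 (72.5%) had an interval (adjusted permutation p = 0.00073), among them the cytoplasmic actins Actg1 (679.84) and Actb (271.74), the dynein heavy chain Dync1h1 (375.24), Actn1 (322.5), the actin-severing protein gene Cfl1 (305.91) and the intermediate filament gene Vim (168.98). Of 40 receptors and effectors of the Wnt, TGF-beta, Notch and Hedgehog pathways 31 (77.5%) had one (adjusted permutation p = 0.00073). The best were at the Wnt receptors Fzd2 (490.82), Fzd7 (353.01) and Fzd5 (273.89) and at the BMP receptor Bmpr2 (314.38), and Notch1, Notch2, Notch3 and Notch4 all had one, with scores from 80.55 to 227.39. Cell junction genes, with 15 of 36 (41.67%), did not pass (adjusted permutation p = 0.18). Their best intervals were at the polarity gene Pard3 (321.21), Afdn (240.82, shared with Tcte2), Vcl (146.57) and Plec (142.81, shared with Parp10), while Tjp1, Gja1 and Itgb1 had none. With genes that have a second gene end within 1 kb left out, 13 of 27 junction genes had an interval and the list passed (adjusted permutation p = 0.018). The cytoskeleton list differed from the junction list (odds ratio 3.69, Fisher's exact p = 0.010, adjusted p = 0.024), but not with 5 kb windows or anywhere in the record (odds ratio 3.0 and adjusted Fisher's exact p = 0.076 in both), and stood at the threshold without genes that have a second gene end within 1 kb (adjusted p = 0.05).

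Several genes that define Sertoli cells, the somatic cells that nurse the germ line, had intervals, although the list as a whole was not detectably above random lists. An interval lay at 12 of 30 Sertoli cell genes (40%, 27.15% in random lists, adjusted permutation p = 0.28). Wt1, a transcription factor gene needed for Sertoli cell identity, had the strongest (2:105126450-105128520, score 626.23). The inhibin subunit genes Inhbb (421.1) and Inha (357.46, shared with Obsl1) and the gene of anti-Müllerian hormone, Amh (10:80806020-80807682, 352.5, shared with Jsrp1), followed. The Amh interval covered the higher end of its record (10:80805240-80807679) and stopped short of the lower end. Without strand, whether it lies at the start of Amh or belongs to Jsrp1 is not known here. Sox9, the testis-determining factor downstream of Sry, had 178.8 (11:112782118-112783400), Dmrt1 had 131.37 and the Desert hedgehog gene Dhh 100.06. Gata4 had no interval at an end of its record but 2 inside it, where starts of transcription are not known here. Fshr, Nr5a1, Clu and Cldn11 had none at an end. When only intervals scoring above the median were kept, 10 of the 30 genes still had one and the list passed (adjusted permutation p = 0.039), near enough to the threshold that an earlier draw of random lists did not pass.

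Signals from the somatic niche had intervals in part. An interval was present at 9 of 23 such genes (39.13%, adjusted permutation p = 0.43). Gdnf, the growth factor that maintains spermatogonial stem cells, had one at 15:7809816-7811497 (362.69), and Vegfa (397.09), the Notch ligand gene Jag1 (260.44), Nrtn (223.28) and the chemokine gene Cxcl12 (174.63, 6:117168253-117169573) were the other best. None lay at an end of Kitl or Fgf2, whose nearest intervals were 749.1 kb and 9.7 kb away. Counting intervals anywhere in the gene record or within 1 kb, the list held 14 of 23 and passed (adjusted permutation p = 0.011). The list of pathway receptors and effectors had intervals more often than this list (odds ratio 5.36, Fisher's exact p = 0.0032, adjusted p = 0.011). That difference did not pass with 500 bp windows (odds ratio 3.23, adjusted Fisher's exact p = 0.068), with midpoints (2.29, 0.33) or anywhere in the record (3.03, 0.13).

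Germ cell genes had few intervals, but not detectably fewer than random lists. Taf4b (241.7), Dazl (183.38), Id4 (109.91) and Utf1 (70.47) were the 4 of 30 genes with one (13.33%, adjusted permutation p = 0.21). Ddx4, Pou5f1, Nanos2, Gfra1 and Kit were not among them. The difference between the Sertoli and germ cell lists did not pass correction (odds ratio 4.33, Fisher's exact p = 0.039, adjusted p = 0.068), but did with intervals scoring above the median (0.033), on autosomes only (0.015) and anywhere in the record (0.035). Among markers of the other testis cells, 5 of 18 Leydig and steroidogenic genes had an interval. These were Ptch1 (347.75), Scarb1 (115.77), Fdx1 (112.39), Tcf21 (100.43) and Gli1 (93.4), and Star, Cyp11a1, Cyp17a1 and Insl3 had none. Of 12 peritubular myoid genes 3 had one, at Tpm1 (210.71), Tpm2 (150.09) and Des (72.66), and of 16 endothelial and macrophage genes 3 had one, at Flt1 (109.04), Kdr (81.48) and Eng (72.11, shared with Fpgs). These 3 lists had adjusted permutation p of 1, 1 and 0.82, and none differed from the Sertoli list (smallest adjusted Fisher's exact p = 0.27). With intervals scoring above the median the Leydig (1 of 18) and the endothelial and macrophage list (0 of 16) did, against 10 of 30 Sertoli genes (adjusted Fisher's exact p = 0.041 and 0.031). With 5 kb windows 13 of 30 Sertoli and 8 of 18 Leydig genes had one (odds ratio 0.96), and anywhere in the record 14 of 30 and 8 of 18 (1.09). The endothelial and macrophage list did not differ there either (adjusted Fisher's exact p = 0.39 and 0.15). The testes were not separated into cell types, so no interval can be assigned to one.

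Polycomb, imprinted, Hox and other homeobox genes did not pass as lists. Polycomb and Trithorax genes had intervals at 14 of 34 (41.18%, adjusted permutation p = 0.18), the best at Kdm5b (418.77, shared with Mgat4e), Kmt2c (358.69), Ring1 (338.23, shared with H2-Ke6) and Kmt2a (322.1). This list passed when windows were widened to 5 kb (adjusted permutation p = 0.015) or when the whole gene record was counted (0.0079), but not when the latter was also matched on gene length (0.053). Imprinted genes had 10 of 30 (33.33%, adjusted permutation p = 0.71), at Cdkn1c (298.16), Ube3a (234.02), Plagl1 (181.43) and Dlk1 (112.43) first. Snrpn, whose locus ARID4B is known to regulate in other tissues, had no interval nearer than 752.7 kb to an end of its record. Hox genes had 9 of 39 (23.08%, adjusted permutation p = 0.83), led by Hoxd9 (424.41), a shared interval at Hoxa5 and Hoxa6 (164.45) and Hoxb2 (85.64). With 5 kb windows 19 of 39 Hox genes had one (48.7%, 32.1% in random lists, adjusted permutation p = 0.079). Anywhere in the record 17 of 39 did (43.6%, 30.5% in random lists, adjusted permutation p = 0.15). The Hox share thus turned from below to above random lists, without passing. Neighbouring Hox genes can share an interval, as Hoxa5 and Hoxa6 do, and wider windows allow more of this. Random lists of scattered genes do not reproduce such sharing. Other homeobox regulators had 10 of 40 (25%, adjusted permutation p = 1), with Gbx2 (197.59, shared with a predicted gene), En2 (117.85), Irx3 (111.78) and Six2 (104.26) first.

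Olfactory and vomeronasal receptor genes, and a list of liver, pancreas and skin genes, were nearly free of intervals. A single interval lay at the 1463 receptor genes (adjusted permutation p = 0.00073), at Vmn1r4 (94.26), whose end lies beside that of Nt5c3. None lay at the 24 genes of the other list, such as Alb, Ins2 and Krt14 (0 of 24, which allows up to 12.5%, adjusted permutation p = 0.0011). With only intervals scoring above the median this last list still had 0 of 24, but with 3.54 expected it no longer passed (adjusted permutation p = 0.081). Replication-dependent histone genes had 4 of 64 (6.25%, adjusted permutation p = 0.00073), H1f5 (133.6) and H2ac20, H2ac21 and H2bc21, which shared an interval of score 111.84. Against random lists of the same gene lengths the histone list did not differ (4 observed, 3.52 expected, adjusted permutation p = 1), and near-identical histone copies may not be separable by short reads.

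**Figure D2:**
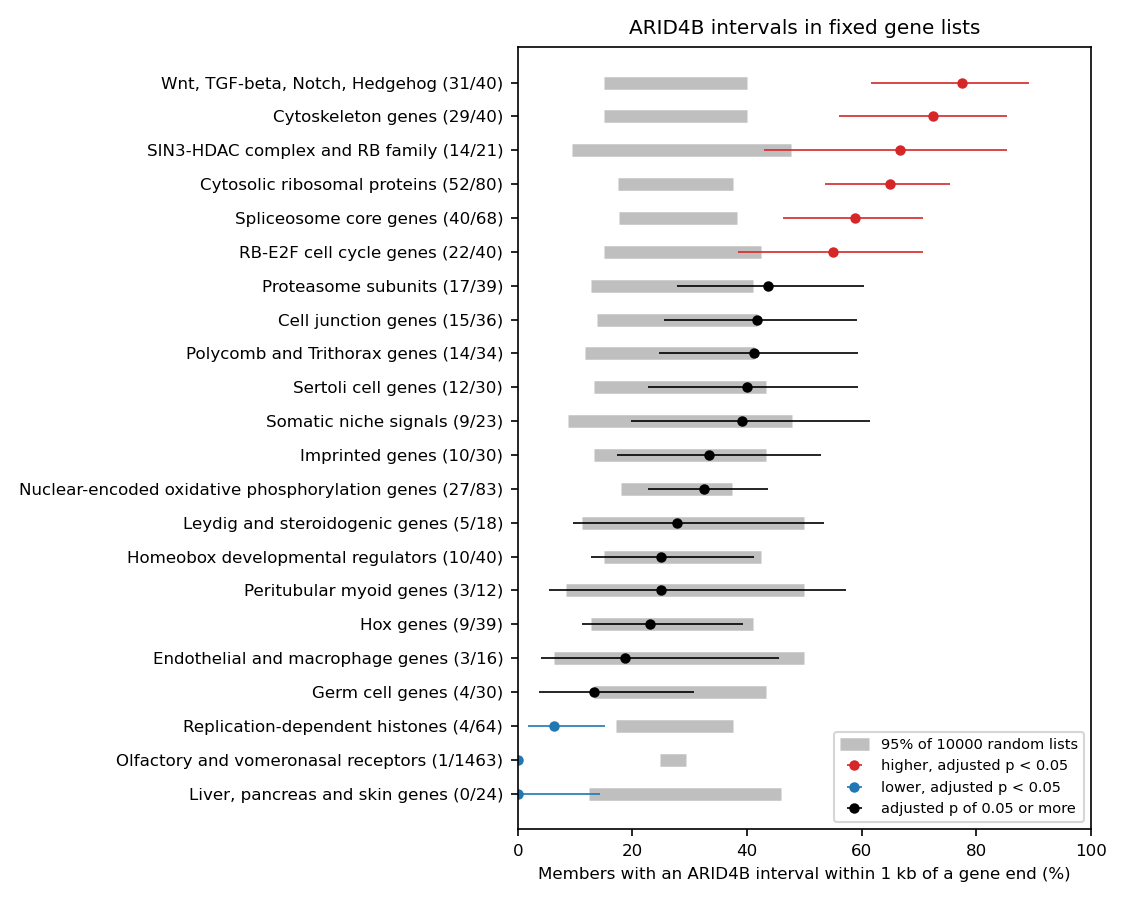
Percent of each list's protein-coding members with an interval within 1 kb of a gene end (points, with 95% Clopper-Pearson intervals that cover counting error only), against the range of 95% of 10000 random lists of the same size (grey). The 6 lists above the random range with adjusted p under 0.05 run from 55.0% to 77.5%, and the 3 below it from 0.0% to 6.25%. The histone list is no longer below when random lists are matched on gene length.

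The X chromosome had far fewer intervals than any autosome. It held 29 intervals, or 0.17 per Mb, while the autosomes held between 1.75 and 5.16 per Mb. An interval lay at 25 of 966 X-linked protein-coding genes (2.59%, 95% Clopper-Pearson interval 1.68 to 3.80%) and at 5905 of 20665 autosomal genes (28.57%, 27.96 to 29.20%), an odds ratio of 0.066 (Fisher's exact two-sided p = 2.8e-99). The lowest autosome was chromosome 7 with 20.05% and the highest chromosome 12 with 35.35%. Without olfactory and vomeronasal receptor genes chromosome 7 had 25.23% and the autosomes together 30.74%. The best X-linked interval was at Msl3 (288.04), an ortholog of a fly dosage compensation gene, followed by Clcn5 (176.33), Nhs (153.35) and Efnb1 (146.21). X-linked intervals had a median score of 92.2, below the lowest autosomal median of 115.1 on chromosome 6. No interval lay at the 256 protein-coding genes of the Y chromosome, which by count alone allows up to 1.17%. Whether an interval could have been placed at them is not known. The treatment of reads that map to several places is not given, and the notes name mm9. The 0 is therefore not read as low binding.

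**Figure D3:**
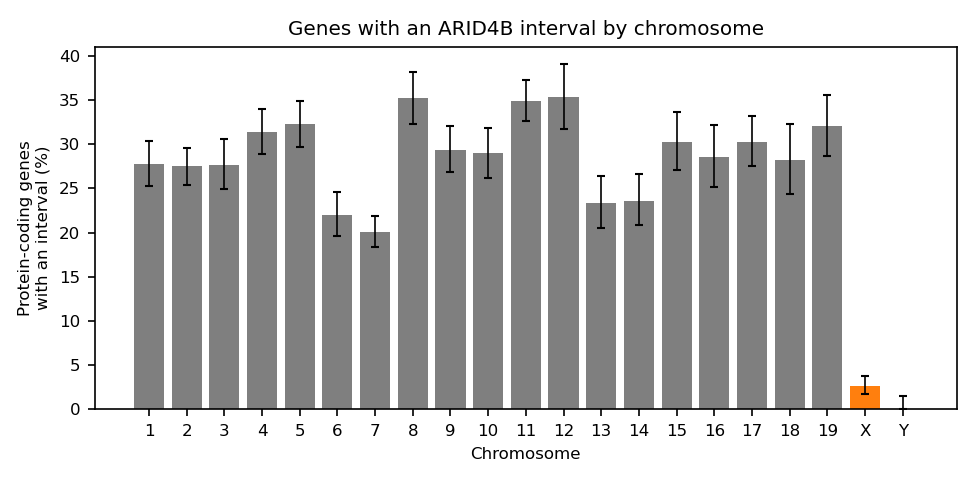
Percent of protein-coding genes with an interval within 1 kb of a gene end on each chromosome (bars, autosomes grey, X and Y orange), with 95% Clopper-Pearson intervals that cover counting error only. The X chromosome stands at 2.59%, against 20.05% to 35.35% on the autosomes.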

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

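Tests with random lists matched on length, curated transcripts, autosomes only, intervals anywhere in the gene record and the wider gene-end class were chosen after the data were examined. The share of intervals at gene ends stayed above shuffles in each of the 6 alternatives run for it, from 77.04% to 93.97%. The number of protein-coding genes with an interval fell to 3237 with intervals scoring above the median and otherwise lay between 5409 and 7023. Midpoints at gene ends made up 84.09% when the class reached 5 kb outside the record. Between 8 and 12 lists passed under the 10 alternatives, against 9. In 7 of the 9, direction and call held under all 10: SIN3-HDAC, cytoskeleton, RB-E2F, ribosomal protein, spliceosome, signalling pathway and olfactory receptor genes. With scores above the median, Sertoli cell genes passed (adjusted permutation p = 0.039, as are the values in brackets below) and liver, pancreas and skin genes, still 0 of 24 but with 3.54 expected, no longer did (0.081). The Sertoli call is near the threshold, and an earlier draw of random lists did not give it. Proteasome subunits passed with 500 bp (0.043), 5 kb (0.019) and midpoints (0.036), and Polycomb and Trithorax genes with 5 kb (0.015). Without genes that have a second gene end within 1 kb, cell junction genes passed (0.018) and histones, with 1 of 22 against 4.89 expected, did not (0.12), though the share was as low as before. Matched on length, histones turned to slightly above the random lists (adjusted permutation p = 1), at gene ends and anywhere in the record alike. In the shortest decile 3.70% of genes had an interval. Many receptor genes are short too, since random lists matched on their lengths had 8.7%. The matching therefore sets histones partly against receptor genes, and an effect of length alone was not shown. Counted anywhere in the record, niche signals (0.011), junction (0.041) and Polycomb and Trithorax genes (0.0079) passed, and matched on length as well only niche signals still did (0.044). Of 3 pairs of lists that differed, all chosen late, ribosomal protein against oxidative phosphorylation genes alone did so under all 8 alternatives that can change the counts. Keeping only genes with a curated transcript left the counts of every pair as they were, so that alternative adds no check. Where not stated, the cause was not tested. Lists matched on promoter CpG content, 5' ends alone, the promoter class by strand, and all CpG and motif alternatives were not run, as they need sequence or strand. Broadly used genes often have CpG-rich promoters, so how far the called lists follow CpG content is open. No expression or open chromatin values were used, so how far the called lists follow gene activity is open too. The unknown read depth limits what a missing interval shows, and a gene without one is only below the authors' limit.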

Other observations

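Gene families grouped by the shared root of their symbols gave a wider view than the fixed lists (271 roots with at least 10 genes, grouped after the data were examined, exact hypergeometric test, Benjamini-Hochberg adjusted). At an adjusted p under 0.05, 20 families had intervals more often than all protein-coding genes and 35 less often. Translation initiation factors (Eif) had intervals at 34 of 56 genes (60.7%, adjusted exact p = 1e-05), Eif5, Eif4a1 and Eif4a2 first. Protein phosphatase genes (Ppp) had 41 of 77, serine-arginine splicing factors (Srsf) 10 of 11, ubiquitin pathway genes (Ube) 24 of 42, and mitochondrial ribosomal protein genes 16 of 29 (Mrps) and 23 of 49 (Mrpl). Some transcription factor families were among the high ones, with Klf at 12 of 17 (Klf16, Klf13 and Klf9 first), Zbtb at 23 of 41 and Sox at 11 of 19 (Sox4, Sox12 and Sox13 first, adjusted exact p = 0.047), while others were not, such as Zfp with 98 of 397 (24.7%, adjusted exact p = 0.48), Nr with 9 of 26 and Pou with 2 of 16.

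Among the low families, keratins (Krt) had none of 53 (up to 5.66% allowed), cytochromes P450 (Cyp) 4 of 99, with Cyp51 of cholesterol synthesis first, and interleukins and their receptors (Il) 8 of 83. Claudins (Cldn), the membrane proteins of tight junctions, had 1 of 35, at Cldn5 (adjusted exact p = 0.0057). More families of immunity and metabolism were low, such as Defb with 0 of 42, Ugt with 0 of 22, Nlrp with 0 of 18 and Ccl with 1 of 25 (adjusted exact p from 9.2e-05 to 0.04). Some did not differ detectably from all genes, such as Traf with 5 of 10, Aldh with 5 of 21 and the solute carriers (Slc) with 108 of 375.

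The 3 patterns below were noticed in the data first, and each test was written before its own value was seen. The first is the low number of X-linked intervals. Male cells carry a single X, so fewer reads per bp are expected there. If signal and background both halved and the score fell in proportion, the X-linked share of 2.59% (upper limit 3.80%) would be near the 13.09% of autosomal genes whose interval scores at least 140.0, and it was below that. Gene content alone also falls short. Of broadly used genes in 9 of the fixed lists, 2 of 14 X-linked (Rps4x and Rbbp7) and 244 of 431 autosomal members (56.61%) had an interval. The odds ratio was 0.128 (Fisher's exact p = 0.002, with the 9 lists picked after the X-linked count was seen). Halved depth would lower these X-linked members too, and depth and gene content together were not tested. A background set over the whole genome, against which a halved signal loses score more than in proportion, stays open, since autosomal genes reach the X-linked share only at a score of 308.6, or 4.41 times the lowest, and no read counts were at hand. Lower ARID4B binding on the X of testis cells may add to it as a hypothesis and cannot be told apart from that effect here.

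The second pattern is that, among intervals at protein-coding gene ends, the best-scoring ones lay at short genes. Genes at the 100 best intervals had a median length of 11.1 kb and the other genes with an interval 24.8 kb (permutation p = 1e-05, the smallest that 100000 resamples can give). Wide intervals that cover both ends of a short gene do not account for all of this, although the gap is smaller without them. Among genes with 1 end outside the interval the medians were 17.8 and 26.6 kb (permutation p = 0.021). Both comparisons leave out intervals over 1 kb inside a record, such as the high-scoring ones in Midn, Ptch1, Gata4, Tnrc18 and Smad7. An interval in a short gene is more easily within 1 kb of an end, so the window itself may favour short genes. Whether it does so more among the best intervals than among the others was not tested. A GC-rich body in genes of few exons may also draw ChIP signal, which needs sequence and stays untested, so no biological reading is offered.

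The third pattern is the gap between ribosomal protein and oxidative phosphorylation genes. Isoforms of restricted tissues in both lists, such as Cox8b and Rpl3l, do not make it: without them 52 of 76 and 27 of 77 genes had an interval (odds ratio 4.01, Fisher's exact p = 4.8e-05, isoforms picked after the intervals were seen). Intervals lent by neighbouring genes do not produce it: without a second gene end within 1 kb, 34 of 51 ribosomal protein genes and 6 of 35 oxidative phosphorylation genes had an interval (odds ratio 9.67, Fisher's exact p = 7.2e-06). Weaker signal that falls below the authors' limit at the latter stays open: scores were lower where an interval was present (median 121.8 for 27 genes against 261.8 for 52, permutation p = 0.004), but 21 of those 27 genes, and 18 of the 52, have a second gene end within 1 kb, to which the interval may belong. Without such genes the medians were 111.0 for 6 genes and 225.4 for 34 (permutation p = 0.17), a comparison added after the former was seen.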
